A study of Mus musculus with 95 samples.

How the data were processed

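The series profiled messenger RNA in the cerebral cortex of mice that carry 1 copy of a Huntington's disease allele. In these knock-in lines a stretch of CAG repeats of a chosen length replaces the normal repeat in the mouse huntingtin gene, Htt, and the lines are named after that length (Q20, Q50, Q92 and Q140). Animals of both sexes were sampled at 6 and at 10 months on a C57BL/6 background. Per the labels, wild-type mice came from cages shared with Q20 mice or from cages shared with Q50 mice, while Q92 and Q140 mice were housed with their own line. Wild types housed with Q92 or Q140 mice were not analysed here. Per the labels, total RNA was extracted from frozen tissue with the Qiagen miRNeasy kit and Illumina libraries were made from an enriched RNA fraction. The labels list 95 libraries in 24 groups of line, age and sex, with 4 libraries each except for the 3 of male Q140 mice at 10 months. The labels number the libraries within each group and do not state that each is a separate animal, so the p-values measure only the spread between these libraries.

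The deposited tables hold estimated counts per gene and FPKM per gene, the latter scaled to gene length and depth by the authors. Of the nonzero estimated counts 67% were whole numbers. Base calling used CASAVA 1.8.2, per the submitters' processing notes. The aligner, the counting tool, the genome build, the annotation and the use of strand are not given in the sources used here. No coordinates are printed for that reason, and RefSeq gene models (assembly GRCm38.p6) served only to tell which genes neighbour Htt. The deposited table has 39179 genes, and 37607 identifiers were paired with a symbol. How reads shared between near-identical copies were counted is not given, so values of predicted genes and pseudogenes (names starting with Gm, or ending in ps) are uncertain. Overlapping and antisense genes are uncertain for the same reason. The summed estimated counts per library lay between 30.3 M and 41.1 M, with a median of 34.1 M.

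Estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15) on the groups of line and sex, libraries were scaled by TMM, and the quasi-likelihood test (legacy = FALSE, robust = TRUE) was run. All libraries of an age shared 1 fit with sex as a covariate. This left 17716 genes at 6 months, 17813 at 10 months and 18187 in the fit of both ages. That fit had a sex term for each age, shared by all lines. Its age difference in wild types is therefore taken at the male level. The CAG trend was fitted over the 4 knock-in lines alone, per 100 repeats. Q20 and Q50 mice were compared with the wild types of their own housing, and Q92 and Q140 mice with the mean of both wild-type groups. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Errors of log2 fold changes are standard errors (SE), and errors of counts scaled to library size (CPM) and of marker levels are standard deviations (SD). In the log2 CPM used for marker levels, the prior count was 1.

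Before the data were examined, 36 gene lists of cell types and pathways, and a list of 5 sex-linked genes, were fixed. Each was tested with fry, whose directional p asks whether the genes of a list move, on balance, in a single direction without comparing the list with other genes. The p-values were adjusted together over the 288 tests of the 36 lists in the 8 comparisons of a line with wild type. Those of other comparisons were adjusted over the lists of that comparison. Beside fry, camera was run with the correlation between genes estimated and with a preset value of 0.01. After the data were seen, lists of 7 forebrain cholinergic neuron genes (among them Chat, Slc5a7, Slc18a3, Lhx8, Slc10a4 and Gbx1), olfactory bulb genes and pituitary hormone genes were added as marker levels.

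Named genes followed a rule fixed before the data were examined. They are Htt, the 8 largest rises and the 8 largest falls of each comparison of a line with wild type among called genes of at least 1 CPM with the same sign in both sexes, and up to 4 called members with the smallest p in each list described. For the trend, age, sex and interaction comparisons 5 rises and 5 falls were taken without the condition on sex. The rule does not mention the comparison between the wild-type groups, where 5 and 5 were also used. Genes outside the rule are said to have been chosen after their values were seen.

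The alternatives were DESeq2 1.42.0 (size factors alone, or its Wald test), limma 3.58.1 (voom with quality weights on counts, or a trend fit on log2 of the deposited FPKM plus 0.1 or plus 1, for genes with a mean FPKM of at least 0.5), no filter and a filter at a mean of 5 CPM. Further alternatives were 3 surrogate variables from sva 3.50.0, the replicate number as a block, and the L code in the sample names as a factor. The 9 libraries whose names carry no D code formed a single level of that factor, whatever their L code. Leaving out these 9 libraries was another alternative. Other references, each sex alone, the compared groups alone, and leaving out each library in turn were also run. Called genes were also counted at an estimated fold of at least 1.2, without a test against that fold. After the data were seen, a covariate (the mean log2 CPM of the cholinergic genes), leaving out the 2 libraries with over 13% mitochondrial counts, and leaving out the knock-in libraries with Abhd1 in the wild-type range were added. What the L and D codes stand for is not given in the sources used here. The tests were also checked on simulated counts in which 200 genes of over 1 CPM were changed. Genes were drawn independently, with no difference in tissue or cohort. The simulated wild-type groups at 6 months differed in 0 genes, against 16 in the real counts. For Q140 against wild type at 6 months, over 17691 genes, edgeR recovered 95.5% of the genes changed 1.5-fold and 100% of those changed 2-fold, with 15 false calls among 201. For the comparison of the Q140 effect between the sexes at 6 months, over 17671 genes, it recovered 67.2% and 92.4%. The closest pair of libraries of a group differed by a chi-square of 4.15 per gene (median 10.2 over 141 pairs), so no library was taken as a copy of another. Xist and Ddx3y matched the labelled sex in each of the 95 libraries.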

Results

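Messenger RNA of the cerebral cortex was measured in mice with a single huntingtin allele carrying 20, 50, 92 or 140 CAG repeats and in wild-type mice, at 6 and 10 months. There were 48 libraries at 6 months and 47 at 10 months, in 24 groups of line, age and sex with 4 libraries each, except for the 3 of male Q140 mice at 10 months. Each age had 16 wild-type libraries, 8 from cages shared with Q20 mice and 8 from cages shared with Q50 mice. The total count per library lay between 30.3 M and 41.1 M (median 34.1 M). A line was compared, over both sexes, as 8 libraries (7 for Q140 at 10 months) with 8 wild types (Q20 and Q50) or 16 (Q92 and Q140). Values after ± are SE for log2 fold changes and SD for marker levels and for CPM, the counts scaled to library size.

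Htt, the huntingtin gene (ENSMUSG00000029104), is the gene that the knock-in changes, and its level was the first question for each line. At 10 months Htt in Q140 mice fell by 0.17 ± 0.045 on the log2 scale (adjusted p = 0.040, lower in 7 of 7 libraries), from 221 ± 20 CPM in the 16 wild types to 196 ± 14 CPM. At 6 months the Q140 value was -0.15 ± 0.075 (adjusted p = 0.34, lower in 8 of 8 libraries), which did not pass the test. All lines of an age share the estimate of spread. At 6 months the SD of Htt was 37 and 40 CPM in Q50 and Q92 mice, against 12 CPM in Q140 mice. The missing call at 6 months therefore does not show that the ages differ. In the other lines Htt did not pass it either, with log2 differences of 0.071 ± 0.085, -0.012 ± 0.086 and 0.075 ± 0.074 for Q20, Q50 and Q92 at 6 months and 0.13 ± 0.050, 0.098 ± 0.050 and 0.078 ± 0.043 at 10 months. Over the 4 knock-in lines and at 10 months, Htt fell by 0.22 ± 0.039 per 100 repeats (adjusted p = 0.0027), while the slope at 6 months was -0.15 ± 0.080 (adjusted p = 0.51). The 10-month levels were 237 ± 7.5, 242 ± 9.5, 233 ± 11 and 196 ± 14 CPM in Q20, Q50, Q92 and Q140 mice. The level was thus not graded, the fall lay in Q140 mice, and each line was a cohort of its own. With the L code of the sample names as a factor the 10-month slope was -0.20 and no longer called (adjusted p = 0.089). The Q140 call at 10 months was not made from FPKM plus 0.1, and it ended when any of 15 libraries was left out. The adjusted p was 0.053, 0.12 and 0.14 without Q140_10mo_Female replicates 1, 2 and 4, and 0.053 and 0.077 without Q140_10mo_Male replicates 2 and 3. It was 0.056, 0.057, 0.052 and 0.061 without WTwithQ20_10mo_Female replicates 1, 2, 3 and 4, and 0.061, 0.054 and 0.052 without WTwithQ20_10mo_Male replicates 1, 3 and 4. It was 0.055 without WTwithQ50_10mo_Female replicate 2, and 0.051 and 0.056 without WTwithQ50_10mo_Male replicates 2 and 4.

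**Figure D1:**
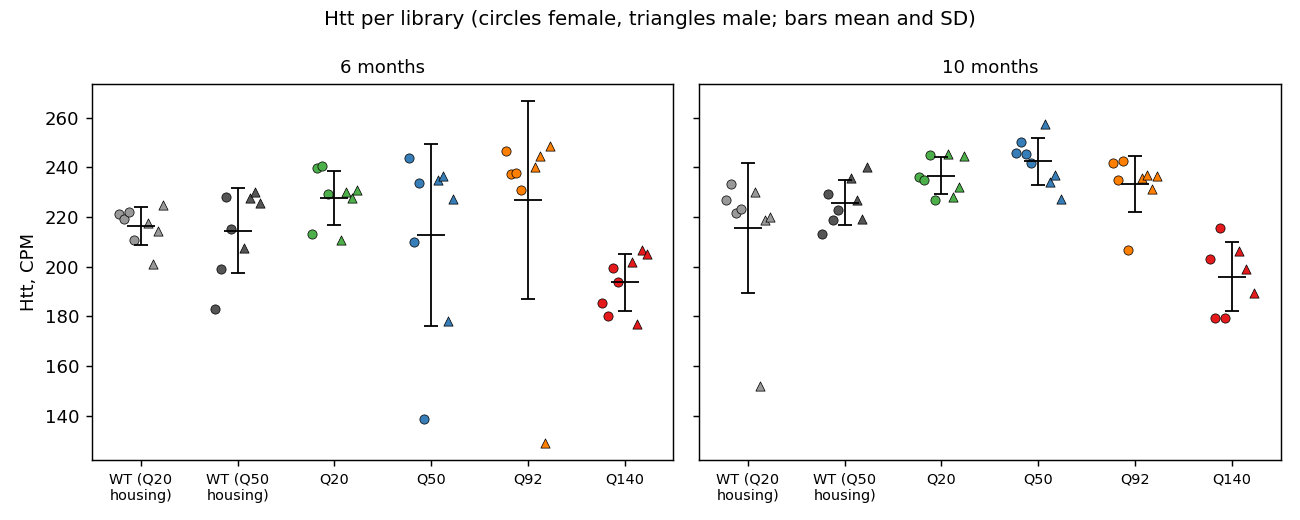
Htt level in CPM (vertical axis) in each library, by line and age (horizontal axis), with the mean and SD of each line. Q140 mice averaged 194 CPM at 6 months and 196 CPM at 10 months, against 216 and 215 CPM and 216 and 226 CPM in the wild-type groups of those ages.

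Q20 mice carry a repeat in the normal range, and at 6 months they differed from their wild-type cage mates in 3 genes of 17716. Abhd1, which encodes a protein with an alpha/beta hydrolase fold (ENSMUSG00000006638), rose by 1.68 ± 0.14 (adjusted p = 3.9e-12), to 5.13 ± 0.60 against 1.59 ± 0.20 CPM, and was higher in 8 of 8 libraries. Atraid, which encodes a membrane protein of the retinoic acid response, fell by 0.33 ± 0.058 (adjusted p = 0.0058), and the predicted gene Gm2420 rose by 2.05 ± 0.35 from a very low level. In Q50 mice at 6 months 4 genes rose, Abhd1 by 1.44 ± 0.14 (adjusted p = 1.1e-09) and the predicted genes Gm2420, Gm5067 and Gm10471 by 1.90 ± 0.36, 1.34 ± 0.25 and 2.50 ± 0.45. The predicted genes were chosen after their values were seen. The Q50 count of 4 became 8 without Q50_6mo_Female replicate 1, 1 without Q50_6mo_Male replicate 2, WTwithQ50_6mo_Male replicate 2 or WTwithQ50_6mo_Male replicate 4, and 2 without Q50_6mo_Male replicate 4 or WTwithQ50_6mo_Male replicate 3. None of the 36 gene lists was called in Q20 or Q50 mice at 6 months.

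Some of these genes recurred across lines. Abhd1 and Gm2420 rose in all 8 comparisons of a line with wild type, Atraid fell in 7 and missed the threshold in Q50 mice at 6 months (-0.18 ± 0.058, adjusted p = 0.80), and Gm5067 and Gm10471 rose in the 6 of Q50, Q92 and Q140 mice but were not called in Q20 mice. All 5 genes called in at least 6 comparisons lie within 10 Mb of Htt on chromosome 5, a window that holds 0.944% of the other genes with a known place (Fisher's exact test, two-sided, p = 8.3e-11, 16418 genes). This test was chosen after the result was seen. The list of genes neighbouring Htt that was fixed before the data were examined was not called in any line. The rise of Abhd1 lay between 1.40 ± 0.15 (Q20, 10 months) and 1.73 ± 0.15 (Q50, 10 months), and its slope per 100 repeats at 10 months was 0.16 ± 0.11 (adjusted p = 0.58). Drc1, which encodes part of the dynein regulatory complex of cilia, rose in Q92 and Q140 mice at both ages and in Q50 mice at 10 months (0.26 ± 0.043), where its values in Q20 mice were -0.0074 ± 0.052 and 0.015 ± 0.043. Its slope per 100 repeats was 0.18 ± 0.047 at 6 months (adjusted p = 0.042) and 0.12 ± 0.046 at 10 months (adjusted p = 0.22), and those of Gm5067 were 0.54 ± 0.19 and 0.50 ± 0.21 (adjusted p = 0.17 and 0.28). In 2 knock-in libraries Abhd1 lay within the wild-type range, Q20_10mo_Male replicate 4 (log2 CPM 0.37) and Q50_6mo_Female replicate 1 (0.91).

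**Figure D2:**
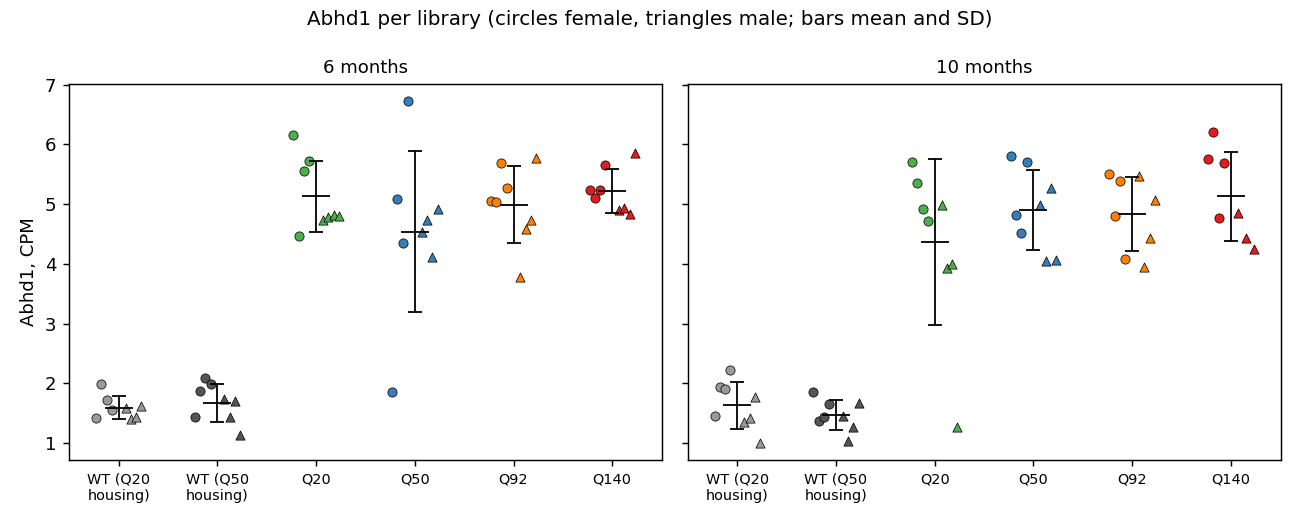
Abhd1 level in CPM (vertical axis) in each library, by line and age (horizontal axis), with the mean and SD of each line. Knock-in libraries sit above the wild types in every line except for Q20_10mo_Male replicate 4 and Q50_6mo_Female replicate 1. On the log2 CPM scale, which is not the one drawn, these 2 libraries were at 0.37 and 0.91.

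At 6 months Q92 mice had lower levels of the genes of striatal projection neurons than wild types. Penk, which encodes the opioid precursor proenkephalin, fell by 1.69 ± 0.17 (adjusted p = 1.8e-08), to 35.7 ± 5.1 against 117 ± 31 CPM, Drd1, the D1 dopamine receptor (-1.12 ± 0.13), and Tac1, the substance P precursor (-1.48 ± 0.17), each in 8 of 8 libraries. Of the 30 fixed striatal markers 29 fell and none rose (list median -0.83, adjusted p = 7.0e-07, and 0.0024 with an estimated correlation), and 29 fell when adjusted over the list alone. Forebrain cholinergic neuron genes, chosen as a group after the data were seen, fell further: the transcription factor gene Lhx8 (-5.03 ± 0.65), Chat, the acetylcholine-making enzyme (-2.95 ± 0.39, 0.371 against 3.05 CPM), and the transporter gene Slc10a4 (-4.06 ± 0.51). Isl1 and Six3, transcription factor genes of striatal and basal forebrain neurons, fell (-4.27 ± 0.52 and -3.12 ± 0.43), and Eomes, a marker of olfactory bulb projection neurons (-4.85 ± 1.28). The mean log2 CPM of 7 cholinergic genes was -2.36 ± 0.45 in Q92 mice, against 1.55 ± 0.34 and 0.64 ± 0.55 in the wild types housed with Q20 and Q50 mice, and with it as a covariate the striatal list was no longer called (adjusted p = 0.62). That level lay between -2.95 and -1.51 in Q92 mice and between 0.00077 and 2.03 in wild types, so the covariate nearly stands for the line and a lost call was to be expected.

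Other lists fell on balance in Q92 mice at 6 months, with members moving both ways. Among 19 interneuron markers 8 fell and 3 rose (median -0.15, adjusted over the list alone 9 and 4), led by Gad2, which makes GABA (-0.55 ± 0.074), and Slc32a1, which loads it into vesicles (-0.37 ± 0.063). Of 10 thalamus and hypothalamus markers 4 fell, among them Tcf7l2 (-0.67 ± 0.11) and Trh (-2.09 ± 0.40), and 1 rose (adjusted over the list alone 6 and 2). Of 25 neuropeptide and neurotrophin genes 7 fell, such as Nts, the neurotensin precursor (-2.28 ± 0.31), and 2 rose (alone 7 and 4). Of 32 cyclic nucleotide and RGS genes 13 fell, such as Rgs9 (-1.57 ± 0.22) and Gng7 (-0.81 ± 0.10), and 3 rose (alone 15 and 5). The adjusted p-values were 0.011, 0.0030, 0.0051 and 0.0015, and the calls were lost with an estimated correlation (adjusted p = 0.41, 0.24, 0.29 and 0.24). Penk, Tac1, Rgs9 and Gng7 are also striatal markers. Over all genes 584 rose and 803 fell, a total that became 748 against the wild types housed with Q50 mice alone, 459 in females, 433 in males and 11 with the cholinergic covariate. Cldn1, a tight junction gene, rose by 0.79 ± 0.22, and choroid plexus genes such as Ttr, the thyroid hormone carrier, rose on average by 2.68 ± 0.84 but were higher in only 4 of 8 libraries. The call for Ttr ended without any of 10 libraries: Q92_6mo_Female replicate 4 (adjusted p = 0.13), Q92_6mo_Male replicates 1, 2 and 4 (0.062, 0.065 and 0.076), WTwithQ20_6mo_Female and WTwithQ20_6mo_Male replicate 3 (0.052 and 0.056), WTwithQ50_6mo_Female replicate 3 (0.0502), and WTwithQ50_6mo_Male replicates 1, 2 and 3 (0.054, 0.053 and 0.051).

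**Figure D3:**
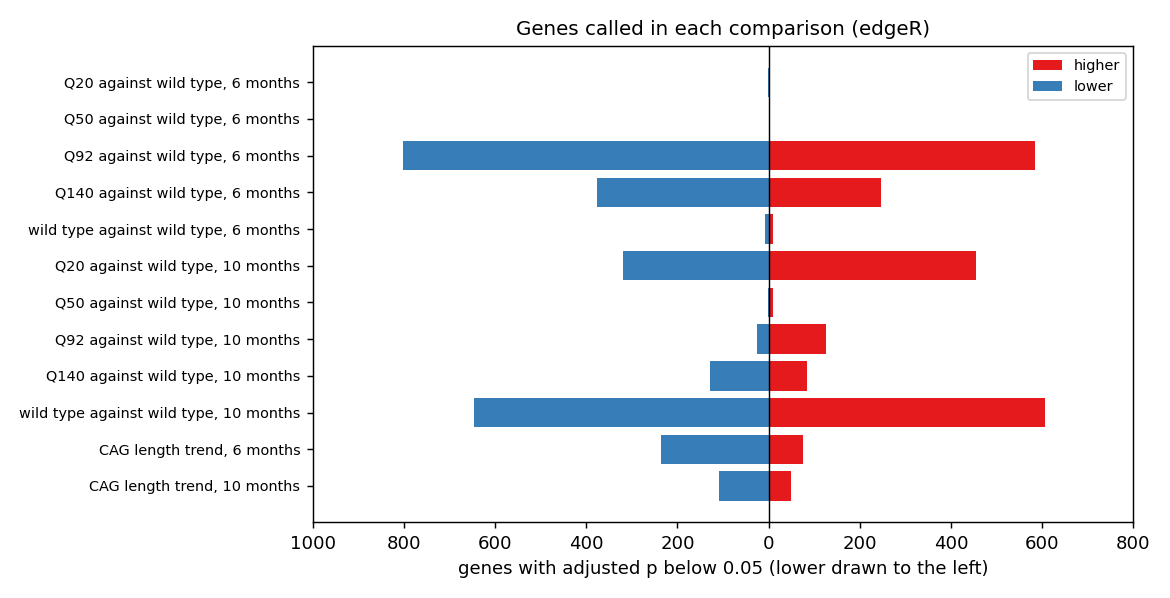
Number of genes called higher and lower (horizontal axis, adjusted p below 0.05, lower drawn to the left) in each comparison (vertical axis). Q92 mice at 6 months had 584 genes higher and 803 lower, and the wild-type groups at 10 months differed in 606 and 646.

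Q140 mice at 6 months showed lower striatal genes too. Penk fell by 1.48 ± 0.17 (adjusted p = 7.6e-07), to 41.4 ± 11 against 117 ± 31 CPM, Drd2, the D2 dopamine receptor (-2.25 ± 0.32), Adora2a, an adenosine receptor gene (-2.01 ± 0.28), and Ppp1r1b, which encodes DARPP-32 (-0.83 ± 0.11), each in 8 of 8 libraries. Of 30 striatal markers 27 fell and none rose (median -0.86, adjusted p = 2.5e-06, and 0.0011 with an estimated correlation), and 29 when adjusted over the list alone. Lhx8, Slc10a4, Chat and Slc5a7, the choline transporter gene, fell (-3.73 ± 0.54, -3.33 ± 0.46, -2.77 ± 0.38 and -2.24 ± 0.30), and the cholinergic level was -2.04 ± 0.75. With that level as a covariate the striatal list was no longer called (adjusted p = 0.72), which was to be expected here too, since the highest level in Q140 mice (-0.97) was below that of any wild type. The olfactory bulb level was also lower, at -0.51 ± 0.20 in Q92 and -0.13 ± 0.54 in Q140 mice, against 1.14 ± 0.63 and 1.24 ± 1.38 in the wild types housed with Q20 and Q50 mice. Gad2 fell by 0.45 ± 0.073 among 3 of 19 interneuron markers (alone 8 lower and 1 higher), and Scg2, a secretory granule gene (-0.32 ± 0.057) among 6 of 25 neuropeptide genes (alone 8 and 1). Of 32 cyclic nucleotide and RGS genes 10 fell (alone 12, and 4 higher), and of 10 thalamus markers 1 fell, Tcf7l2 (-0.41 ± 0.11, not called without Q140_6mo_Male replicate 1, adjusted p = 0.064), and 6 adjusted over the list alone. These 4 lists were called (adjusted p = 0.010, 0.0030, 0.0048 and 0.019) but not with an estimated correlation (adjusted p = 0.24, 0.21, 0.24 and 0.29). Ttr, of the choroid plexus, rose by 3.42 ± 0.84 in 5 of 8 libraries, a call that ended without Q140_6mo_Female replicate 1 (adjusted p = 0.069). Over all genes 624 changed, 247 of them upwards, with 3 called in females alone, 262 in males alone, 289 against the wild types housed with Q50 mice alone, 356 with the L code as a factor and 27 with the cholinergic covariate. The count was 1016 without Q50_6mo_Female replicate 4 and Q92_6mo_Male replicate 3, the libraries with over 13% mitochondrial counts, which share the estimate of spread. It was 367 without Q140_6mo_Male replicate 3 and 413 without Q140_6mo_Male replicate 4.

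To set Q92 beside Q140 mice without shared references, Q92 was compared with 1 wild-type group and Q140 with the other. At 6 months 100 genes were lower in both, where 7.69 would be if the lists were independent, and 21 were higher in both, against 2.85. Across genes, which are not independent replicates, the Pearson correlation of the fold changes was 0.38 (jackknife SE 0.16). At 10 months it was -0.17 (SE 0.20), with 6 genes higher in both and 6 lower, against 0.918 and 2.66 if independent. Between the ages the correlation was -0.44 (SE 0.22) for Q92 and -0.12 (SE 0.22) for Q140 mice, 0.065 (SE 0.20) for Q20 and 0.085 (SE 0.18) for Q50 mice. The mean log2 CPM of the striatal markers was 3.59 ± 0.15 and 3.77 ± 0.28 in Q92 and Q140 mice at 6 months, against 5.07 ± 0.26 and 4.57 ± 0.24 in the wild types housed with Q20 and Q50 mice. At 10 months the lowest level was that of the wild types housed with Q20 mice (3.53 ± 0.21), against 4.64 ± 0.50 in those housed with Q50 mice, 4.03 ± 0.62 in Q92 and 4.18 ± 0.53 in Q140 mice.

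**Figure D4:**
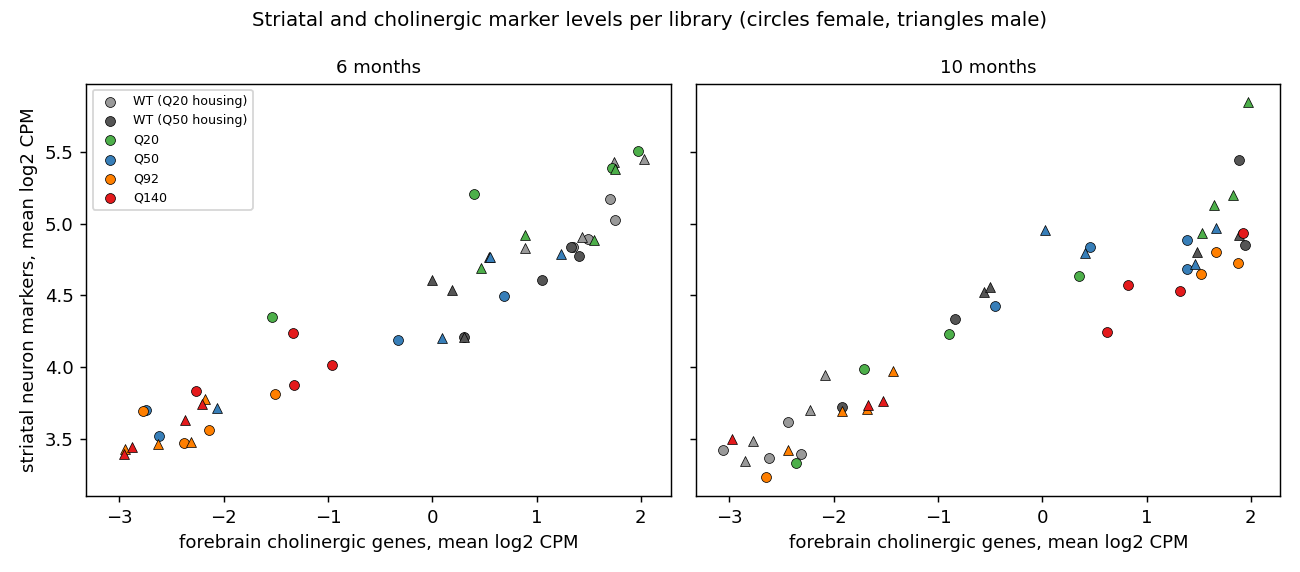
Mean log2 CPM of 30 striatal markers (vertical axis) against that of 7 forebrain cholinergic genes (horizontal axis), a point per library, by line and age. Across the 32 wild-type libraries the striatal level rose by 0.36 ± 0.027 (SE) per unit of the cholinergic level, with age as a term in the fit.

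The comparison of wild types housed with Q20 mice against those housed with Q50 mice shows how far groups of the same genotype differed. At 6 months Gpr37, a receptor gene of oligodendrocytes, was higher by 0.24 ± 0.040 (adjusted p = 0.0033, 8 of 8 libraries). Myelin markers were higher on balance (median 0.16, adjusted p = 0.012, and 0.024 with an estimated correlation; 1 of 17 called, and 12 adjusted over the list alone), as were striatal markers (median 0.50, adjusted p = 0.022, and 0.034 with an estimated correlation, no member called, and 26 adjusted over the list alone). Meningeal markers were lower (median -0.56, adjusted p = 0.012, and 0.024 with an estimated correlation; 2 of 12 called, and 10 alone). Mural cell markers (median -0.22, adjusted p = 0.022, 0.044 with an estimated correlation) and cyclic nucleotide and RGS genes (median 0.073, adjusted p = 0.022, 0.044) were called as lists with no member called, and 5 lower and 6 higher adjusted over the list alone. In all 9 genes were higher and 7 lower. That total of 16 became 28 without Q92_6mo_Male replicate 3, which shares the estimate of spread, and 2 without WTwithQ50_6mo_Male replicate 1. It was 5 without WTwithQ20_6mo_Female replicate 1, WTwithQ50_6mo_Female replicate 4 or WTwithQ20_6mo_Male replicate 2, and 6 without WTwithQ20_6mo_Male replicate 1 or WTwithQ50_6mo_Male replicate 4. It was 8 without WTwithQ50_6mo_Female replicate 2, 9 without WTwithQ20_6mo_Male replicate 3, and 10 without WTwithQ20_6mo_Female replicate 3 or WTwithQ50_6mo_Female replicate 3.

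At 10 months the wild types housed with Q20 mice had lower striatal and meningeal genes and higher glucocorticoid-responsive genes than those housed with Q50 mice. Adora2a was lower (-2.23 ± 0.47, 2.71 ± 1.0 against 12.7 ± 7.8 CPM), and 24 of 30 striatal markers were called lower (median -0.82, adjusted p = 0.0046, alone 28), beside cholinergic levels of -2.55 ± 0.34 and 0.42 ± 1.54. Among 12 meningeal markers 6 were lower, such as Slc22a6, an anion transporter gene (-0.96 ± 0.21), and Col3a1, a collagen gene (-0.94 ± 0.21; median -0.60, adjusted p = 0.0046, alone 11), and of 9 mural cell markers 4, such as Myh11 (-0.59 ± 0.15; median -0.17, adjusted p = 0.013, alone 5). Of 12 glucocorticoid-responsive genes 6 were higher, among them Zbtb16 (0.85 ± 0.12, adjusted p = 0.00015), Mt2 (0.48 ± 0.096) and Tsc22d3 (0.50 ± 0.12; median 0.41, adjusted p = 0.00065, alone 8). None of these 4 list calls held with an estimated correlation (adjusted p = 0.26, 0.26, 0.34 and 0.11). In all 606 genes were higher and 646 lower. The total of 1252 became 803 without WTwithQ20_10mo_Female replicate 1, 785 without WTwithQ20_10mo_Female replicate 4, 775 without WTwithQ50_10mo_Female replicate 1 and 631 without WTwithQ50_10mo_Male replicate 1.

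Q20 mice at 10 months had higher striatal genes than the wild types housed with them, the group in which these genes were lowest. Pde10a, a striatal phosphodiesterase gene, rose by 1.11 ± 0.21 (adjusted p = 0.0086, 180 ± 82 against 83.1 ± 19 CPM), Rgs9 by 1.74 ± 0.33 and Adora2a by 2.37 ± 0.46, each in 7 of 8 libraries. Of 30 striatal markers 26 rose (median 1.09, adjusted p = 0.0072, but 0.24 with an estimated correlation), and 28 when adjusted over the list alone. Cholinergic levels were 0.30 ± 1.73 in Q20 mice and -2.55 ± 0.34 in these wild types. Lhx8 rose by 6.10 ± 1.44 and Slc5a7 by 2.88 ± 0.68, calls that ended without Q20_10mo_Male replicate 4 (adjusted p = 0.057 and 0.064). Prl, the pituitary hormone prolactin, rose by 8.28 ± 1.79 from near 0 in 6 of 8 libraries. Upper cortical layer markers fell on balance (median -0.085, adjusted p = 0.010, 0.33 with an estimated correlation), with 2 of 11 called lower, and 5 lower and 3 higher adjusted over the list alone. Over all genes 456 rose and 319 fell. Females alone called 1 gene and males alone 2332, and 130 were called against the mean of both wild-type groups and 48 with the L code as a factor. The total of 775 became 1997 without Q20_10mo_Female replicate 4, 1292 without WTwithQ20_10mo_Female replicate 2, 485 without WTwithQ20_10mo_Male replicate 3 and 449 without WTwithQ20_10mo_Male replicate 1. It was 342, 302, 137, 131 and 74 without Q20_10mo_Female replicate 2 and Q20_10mo_Male replicates 3, 1, 2 and 4, and 281 and 168 without WTwithQ20_10mo_Female replicate 4 and WTwithQ20_10mo_Male replicate 2.

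In Q50 mice at 10 months 9 genes rose and 1 fell. Abhd1 rose by 1.73 ± 0.15 (adjusted p = 5.5e-11), Drc1 by 0.26 ± 0.043, the unnamed gene 6030443J06Rik by 1.38 ± 0.22 and Gm6410 by 0.74 ± 0.14, and Atraid fell by 0.31 ± 0.040, each in 8 of 8 libraries. No gene list was called in these mice.

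Q92 mice at 10 months had pituitary and olfactory bulb genes in some libraries. Gh, growth hormone, rose by 7.88 (adjusted p = 0.00025, 5.89 against 0.0436 CPM) and Prl by 7.18 ± 0.96, each in 6 of 8 libraries. Eomes rose by 3.62 ± 0.73, a call that ended without Q92_10mo_Female replicate 4 (adjusted p = 0.061), and Shisa3 by 1.57 ± 0.28. The pituitary level (mean log2 CPM of Prl and Gh) was 0.22 ± 3.38, against -4.84 ± 0.37 and -3.12 ± 1.46 in the wild types housed with Q20 and Q50 mice, and the olfactory bulb level was 1.59 ± 1.55, against -0.32 ± 0.15 and 0.49 ± 0.90. Atraid fell by 0.27 ± 0.035 and Ifitm10 (-0.27 ± 0.053). Of the lists, that of upper layer markers was called lower (median -0.050, adjusted p = 0.028, 0.29 with an estimated correlation) with none of its 11 genes called, and 0 lower and 0 higher adjusted over the list alone. Over all genes 126 rose and 26 fell. Against the wild types housed with Q20 mice alone 818 rose and 728 fell, and against those housed with Q50 mice alone 7 and 1. Females alone called 148 and males alone 2, and 59 were called with the L code as a factor. The total of 152 became 443 without Q92_10mo_Female replicate 3, 323 without Q92_10mo_Male replicate 1 and 230 without WTwithQ50_10mo_Male replicate 1. It was 41, 43 and 30 without Q92_10mo_Female replicates 1, 2 and 4, and 85 without Q92_10mo_Male replicate 3.

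In Q140 mice at 10 months the myelin genes were lower. Cldn11, a tight junction gene of myelin, fell by 0.46 ± 0.051 (adjusted p = 4.0e-08), to 61.8 ± 5.8 against 84.6 ± 6.9 CPM, and Mal and Mobp, also of myelin, fell (-0.48 ± 0.056 and -0.46 ± 0.059), each in 7 of 7 libraries. Of 17 myelin markers 10 fell and none rose (median -0.26, adjusted p = 4.9e-06, and 0.0011 with an estimated correlation), and 16 fell when adjusted over the list alone. Il33, an interleukin gene of oligodendrocytes and astrocytes, fell by 0.50 ± 0.056 (adjusted p = 4.6e-08, 49.5 ± 3.9 against 69.3 ± 4.8 CPM), and Pkd2l1, a channel gene (-0.84 ± 0.15). The mean log2 CPM of the myelin markers was 6.37 ± 0.13, against 6.65 ± 0.058 and 6.67 ± 0.076 in the wild types, and that of 10 oligodendrocyte precursor markers was 4.11 ± 0.12, against 4.08 ± 0.050 and 4.10 ± 0.042. Meningeal markers rose beside this (median 0.51, adjusted p = 0.029, but 0.24 with an estimated correlation), with 3 of 12 called and 10 adjusted over the list alone. The meningeal level was 3.75 ± 0.32, against 2.93 ± 0.26 and 3.57 ± 0.18 in the wild types housed with Q20 and Q50 mice. It was thus far closer to that of the wild types housed with Q50 mice. Slc22a6, of the meninges, rose by 0.78 ± 0.17 and Cdh1, E-cadherin, by 0.90 ± 0.21, and both calls ended without Q140_10mo_Female replicate 4 (adjusted p = 0.083 and 0.099). Upper layer markers were called lower (median -0.084, adjusted p = 0.011, 0.24 with an estimated correlation) with no single gene called, and 1 adjusted over the list alone. Over all genes 85 rose and 128 fell. Against the wild types housed with Q20 mice alone 508 rose and 576 fell, and against those housed with Q50 mice alone 20 and 65. In females alone 106 were called, in males alone 14 and with the L code as a factor 97. The total of 213 became 138 without Q140_10mo_Female replicate 1 and 128 without Q140_10mo_Female replicate 4.

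**Figure D5:**
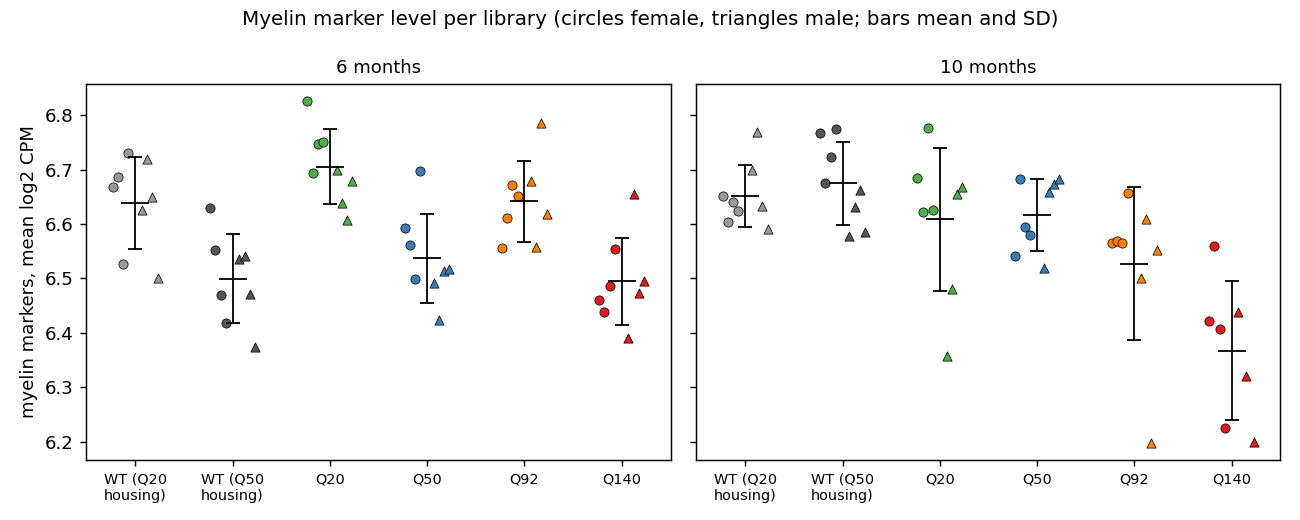
Mean log2 CPM of 17 myelin markers (vertical axis) in each library, by line and age (horizontal axis), with the mean and SD of each line. At 10 months Q140 mice averaged 6.37, against 6.65 and 6.67 in the wild-type groups.

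The CAG trend over the 4 knock-in lines asks which genes are graded with repeat length. At 6 months Drd2 fell by 2.75 ± 0.36 per 100 repeats (adjusted p = 7.2e-05), Penk (-1.49 ± 0.20), Ppp1r1b (-0.94 ± 0.13) and Chat (-3.09 ± 0.42), and 28 of 30 striatal markers fell (median -0.96, adjusted p = 0.00014, and 0.0011 with an estimated correlation), 29 when adjusted over the list alone. The striatal level was 5.04 ± 0.40, 4.17 ± 0.49, 3.59 ± 0.15 and 3.77 ± 0.28 in Q20, Q50, Q92 and Q140 mice. It thus fell no further from Q92 to Q140 mice. In the wild types housed with Q20 and Q50 mice it was 5.07 ± 0.26 and 4.57 ± 0.24. Part of the step between Q20 and Q50 mice was therefore also present between the wild types, and each line was a cohort of its own. Casp1, an inflammatory protease gene, rose by 0.47 ± 0.11. Fa2h, which makes hydroxylated myelin lipids, fell by 0.23 ± 0.044 among 3 of 17 myelin markers (median -0.099, adjusted p = 0.022, 0.12 with an estimated correlation, alone 9). The myelin level was not graded, at 6.71 ± 0.069, 6.54 ± 0.082, 6.64 ± 0.075 and 6.49 ± 0.080 in Q20, Q50, Q92 and Q140 mice, and it was 6.64 ± 0.085 and 6.50 ± 0.082 in the wild types housed with Q20 and Q50 mice. Over all genes 76 rose and 236 fell with repeat length at 6 months, and 161 were called with the L code as a factor and 20 with the cholinergic covariate.

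At 10 months myelin genes fell with repeat length, and meningeal and antigen presentation genes rose. Fa2h fell by 0.39 ± 0.057 per 100 repeats (adjusted p = 0.00021), Ugt8a (-0.36 ± 0.052) and Cldn11 (-0.34 ± 0.049), with 6 of 17 myelin markers lower (median -0.19, adjusted p = 0.0035, and 0.048 with an estimated correlation, alone 12). H2-Ab1 and Cd74, which serve antigen presentation on class II molecules, rose by 0.91 ± 0.18 and 0.74 ± 0.15, and B2m and H2-D1 of class I by 0.18 ± 0.036 and 0.22 ± 0.047, among 5 of 16 interferon and antigen presentation genes (median 0.18, adjusted p = 0.023, but 0.14 with an estimated correlation, alone 5). Meningeal markers rose (median 0.60, adjusted p = 0.011, but 0.099 with an estimated correlation, 2 of 12 called, alone 11), but each line was a cohort of its own. The meningeal level was 2.93 ± 0.28 in Q20 mice and 2.93 ± 0.26 in the wild types housed with them, and 3.50 ± 0.33 in Q50 mice and 3.57 ± 0.18 in theirs, so the step between these lines was also present between the wild types. Astrocyte markers fell (median -0.088, adjusted p = 0.042, but 0.18 with an estimated correlation), with 2 of 15 called, among them the glutamate transporter gene Slc1a2 (-0.15 ± 0.034), and 8 lower and 1 higher adjusted over the list alone. In all 49 genes rose and 108 fell. With the L code as a factor 2 rose and 22 fell, and Fa2h, Ugt8a and Cldn11 were still called, while H2-Ab1, Cd74, B2m, H2-D1 and Slc1a2 were not (adjusted p = 0.15, 0.14, 0.15, 0.12 and 0.22). The total of 157 became 87 without Q140_10mo_Male replicate 3 or Q20_10mo_Female replicate 2, 91 without Q20_10mo_Male replicate 3 and 90 without Q20_10mo_Male replicate 4.

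Female and male wild types differed in genes of the sex chromosomes and in others. Xist, which silences an X chromosome in females, was higher in females by 11.49 ± 0.20 at 6 months and 11.27 ± 0.13 at 10 months, and Ddx3y, on the Y chromosome, lower (-11.95 and -12.58), the other Y genes of the fixed list, Eif2s3y, Kdm5d and Uty, falling too. Eif2s3x, on the X chromosome, was higher in females by 0.58 ± 0.026 and 0.63 ± 0.027, and Dbp, a clock gene, by 0.47 ± 0.065 at 6 months. In all 14 genes were higher and 7 lower at 6 months, and 17 and 6 at 10 months. The Q140 effect did not differ between the sexes in any gene by edgeR at either age. At an unadjusted p below 0.05 there were 477 genes at 6 months and 1236 at 10 months. The DESeq2 Wald test and voom with quality weights also called 0 (411 and 798 genes at unadjusted p below 0.05 at 6 months, 1207 and 1461 at 10 months). In the simulated data 67.2% of the genes changed 1.5-fold were recovered in this test at 6 months. The marker levels of Q140 mice at 10 months, compared by sex after the values were seen, did not overlap: the cholinergic level lay between 0.62 and 1.93 in the 4 females and between -2.98 and -1.52 in the 3 males, and the striatal level between 4.25 and 4.93 and between 3.50 and 3.76.

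The Q92 effect differed between the ages in 1751 genes, 1070 of them higher at 10 months relative to 6 months. Lhx8 differed by 7.41 ± 1.31, Isl1 by 6.30 ± 1.02, Eomes by 8.47 ± 1.41 and Drd3, a dopamine receptor gene, by 7.12 ± 1.16, and 21 of 30 striatal markers were higher (median 0.85, adjusted p = 0.0027, but 0.21 with an estimated correlation, alone 24). Trf, the transferrin gene, was among 9 of 17 myelin markers that were lower (-0.33 ± 0.070; median -0.23, adjusted p = 0.0027, but 0.21 with an estimated correlation, alone 12), and Thbs4, a thrombospondin gene, was lower (-0.88 ± 0.15). Fmod was among 7 of 12 meningeal markers that were higher (1.02 ± 0.25; median 0.63, adjusted p = 0.026, but 0.55 with an estimated correlation, alone 10). With the cholinergic level as a covariate edgeR called 0 genes (964 at unadjusted p below 0.05). This comparison uses wild types whose striatal and cholinergic levels themselves differed by age and cage, as given for the wild types. A batch that follows age cancels in the Q92 and Q140 differences between the ages only if it acts alike on both genotypes.

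The Q140 effect differed between the ages in 325 genes, 221 higher at 10 months relative to 6 months and 104 lower. Chat differed by 3.73 ± 0.78 and Lhx8 by 6.18 ± 1.18, and 18 of 30 striatal markers were higher (median 0.94, adjusted p = 0.0025, 0.054 with an estimated correlation, alone 26). Of 17 myelin markers 6 were lower (median -0.22, adjusted p = 0.0025, 0.054 with an estimated correlation, alone 13), and Slc22a6 was higher by 1.19 ± 0.25 among 8 of 12 meningeal markers (median 0.86, adjusted p = 0.0025, 0.054 with an estimated correlation, alone 10). There were 38 genes higher and 11 lower with the L code as a factor, and with the cholinergic level as a covariate edgeR called 0 (1156 at unadjusted p below 0.05). The total became 44 without Q140_10mo_Female replicate 4, 156 without Q140_10mo_Female replicate 3, and 203, 120, 139 and 200 without Q140_6mo_Male replicates 1, 2, 3 and 4.

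Between 6 and 10 months 556 genes rose and 1197 fell in wild types. The difference was taken at the male level, with a sex term of each age shared by all lines. Penk fell by 0.82 ± 0.20, Tac1 (-0.84 ± 0.21) and Lhx8 (-3.29 ± 0.76), with 21 of 30 striatal markers lower (median -0.54, adjusted p = 0.0085, but 0.70 with an estimated correlation, alone 24). Sst, the somatostatin gene, fell by 0.26 ± 0.065 and Vip rose by 0.23 ± 0.054 among neuropeptide genes, of which 6 fell and 1 rose (median -0.13, adjusted p = 0.013, but 0.70 with an estimated correlation, alone 6 and 1). The total of 1753 became 77 with the L code as a factor, where none of these 5 genes was called (adjusted p from 0.091 for Vip to 0.39 for Sst), 600 with a block of the replicate number and 531 with 3 surrogate variables, where Sst turned to 0.014. The L code and the replicate number had separate terms within each age. Those fits took the age difference at the first code or number of each age. The counts of 77 and 600 and the lost calls therefore do not show whether the difference depends on either. With the cholinergic level as a covariate the total was 1036, and Tac1 turned to 0.0079. The labels do not say how libraries of the ages were prepared. The numbers that open the sample names lie in separate ranges at 6 and at 10 months. The same pairs of L and D codes recur at both ages. Age and a batch that follows age therefore cannot be told apart in this comparison. In the wild types housed with Q20 mice the cholinergic level was 1.55 ± 0.34 at 6 months and -2.55 ± 0.34 at 10 months, against 0.64 ± 0.55 and 0.42 ± 1.54 in those housed with Q50 mice.

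Of the 288 tests of 36 lists in the 8 comparisons of a line with wild type, 16 were called, 2 higher and 14 lower. Camera called 3 with an estimated correlation and 79 with a preset correlation of 0.01. In these comparisons 8 lists were called at least once and 28 were not, and the lowest adjusted p among the 28 was 0.056, for nuclear-encoded oxidative phosphorylation genes in Q20 mice at 10 months (median -0.10). Reactive astrocyte, microglia, interferon, heat shock and repeat instability genes were among the lists that were not called. Of the 58 protocadherins fixed, 24 were in the deposited table, and that list was not called in any line.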

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

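The tests of the tissue taken, of the L code and of the repeat length in this part were chosen after the result was seen, and the splits of the samples before.

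The Q92 effect differed between the ages in 1751 genes and the Q140 effect in 325, by a test of the difference itself, and striatal and cholinergic genes were among both, although the striatal list calls were lost with an estimated correlation (adjusted p = 0.21 and 0.054). With the L code as a factor the median of the striatal markers in Q140 mice at 6 months was -0.87, beside -0.86 without it, which argues against that code as the source of the fall at 6 months, although the difference between the ages was then 1690 genes for Q92 and 49 for Q140 mice, and 0 for both by edgeR with the cholinergic covariate (964 and 1156 at unadjusted p below 0.05), which nearly stands for the line at 6 months. The pattern is consistent with less striatum and basal forebrain in the tissue taken (olfactory bulb genes were lower too, at -0.51 ± 0.20 and -0.13 ± 0.54 in Q92 and Q140 mice at 6 months, against 1.14 ± 0.63 and 1.24 ± 1.38 in the wild types): across the 32 wild-type libraries the striatal level rose by 0.36 ± 0.027 (SE) per unit of the cholinergic level, and that slope predicts 104% of the fall in Q92 and Q140 mice at 6 months (92.2% with slopes within groups). The slope was fitted over both ages with a term for age. It was 0.46 in the wild types at 6 months alone and 0.35 in those at 10 months alone. At 6 months the cholinergic levels of Q92 and Q140 mice lay below those of all wild types of that age. At those levels the prediction therefore rests on the wild types at 10 months. An effect of the long repeat cannot be told apart from less striatum and basal forebrain in the tissue taken, since the striatal median in Q140 mice at 10 months against the wild types housed with Q50 mice was -0.38, while it differed (-0.82) between the wild-type groups of that age. A biological difference between the lines stays open and untested. No other split of the samples reached the real count for either difference between the ages. The real counts were 1751 for Q92 and 325 for Q140 mice, and the highest of the other splits gave 72 and 119. Those splits moved single libraries between lines within sex and age, so a difference between cohorts would also set the real split apart. The Q140 count rests in part on single libraries, since it was 44 without Q140_10mo_Female replicate 4.

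Single libraries stood far from the other 3 of their group in 12 of 184 groups over 8 measures, where chance gives about 5%. The total count was 32.0 M in Q50_10mo_Male replicate 4, against 34.1 M to 34.5 M in the others. The striatal level was 3.23 in Q92_10mo_Female replicate 3 (others 4.65 to 4.80) and 3.77 in Q92_6mo_Male replicate 2 (3.43 to 3.48). The myelin level was 6.52 in Q50_10mo_Male replicate 1 (6.66 to 6.68) and 6.66 in Q92_10mo_Female replicate 4 (6.56 to 6.57). The meningeal level was 4.31 in Q140_10mo_Female replicate 4 (3.61 to 3.71). Htt was at 177 CPM in Q140_6mo_Male replicate 2 (202 to 207), 211 in Q20_6mo_Male replicate 1 (228 to 231) and 178 in Q50_6mo_Male replicate 3 (227 to 236). It was at 129 CPM in Q92_6mo_Male replicate 3 (240 to 249) and 152 in WTwithQ20_10mo_Male replicate 2 (219 to 230). Abhd1 was at 5.86 CPM in Q140_6mo_Male replicate 4 (4.83 to 4.94).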

How the results depend on the processing

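The alternatives with the cholinergic covariate, without the libraries above 13% mitochondrial counts and without the knock-in libraries with wild-type-range Abhd1 were chosen after the results were seen. Of 308 counts of called genes or lists under the alternatives, 197 were within 1.5 times the reported count and 111 were not. The values that moved follow, with comparisons named by line or group and age in months ("by age" is the difference of an effect between the ages), and the cause was not tested except where fewer samples or genes explain it. Of 281 results for named genes, DESeq2 size factors left all 281 called in the same direction, the L code 166, 3 surrogate variables 234 and the cholinergic covariate 97. Females alone left 43 and males alone 68 of 133, with fewer samples in each.

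With a filter at a mean of 5 CPM the count was 1 for Q20 at 6, 0 for Q50 at 6 (654 at unadjusted p below 0.05), 374 for Q140 at 6, 3 for Q50 at 10, 187 for trend at 6 and 191 for Q140 by age. In females only the count was 1 for Q20 at 6, 0 for Q50 at 6 (1822 at unadjusted p below 0.05), 459 for Q92 at 6, 3 for Q140 at 6, 1 for Q20 at 10, 1 for Q50 at 10 and 106 for Q140 at 10. In males only the count was 1 for Q20 at 6, 433 for Q92 at 6, 262 for Q140 at 6, 2332 for Q20 at 10, 3 for Q50 at 10, 2 for Q92 at 10 and 14 for Q140 at 10. With limma-voom and quality weights the count was 2 for Q50 at 6, 983 for Q140 at 6, 105 for wild types at 6, 1810 for Q20 at 10, 424 for Q140 at 10, 846 for trend at 6, 300 for trend at 10, 42 for sex at 6 and 2755 for age in wild type. With the L code as a factor the count was 2 for Q50 at 6, 356 for Q140 at 6, 7 for wild types at 6, 48 for Q20 at 10, 59 for Q92 at 10, 97 for Q140 at 10, 657 for wild types at 10, 161 for trend at 6, 24 for trend at 10, 14 for sex at 10, 49 for Q140 by age and 77 for age in wild type. For age in wild type the count was taken at the first L code of each age, so it does not show a dependence on that code. With 3 surrogate variables the count was 7 for Q50 at 6, 2309 for Q92 at 6, 1355 for Q140 at 6, 130 for wild types at 6, 67 for Q20 at 10, 742 for wild types at 10, 993 for trend at 6, 392 for trend at 10, 265 for sex at 6 and 531 for age in wild type. With limma-trend on FPKM plus 0.1 the count was 1 for Q50 at 6, 7 for wild types at 6, 6 for Q50 at 10, 69 for Q92 at 10, 140 for Q140 at 10, 185 for Q140 by age and 0 for calls of Htt. With limma-trend on FPKM plus 1 the count was 1 for Q50 at 6, 6 for Q50 at 10, 64 for Q92 at 10, 138 for Q140 at 10 and 191 for Q140 by age. With the Q20 line as the reference the count was 311 for Q50 at 6, 780 for Q92 at 6, 387 for Q140 at 6, 61 for Q50 at 10 and 407 for Q140 at 10. With the mean of both wild-type groups the count was 26 for Q50 at 6 and 130 for Q20 at 10. With only the groups compared in the fit the count was 2 for Q50 at 6, 502 for Q20 at 10 and 20 for Q92 at 10. With the wild types housed with Q50 mice alone the count was 748 for Q92 at 6, 289 for Q140 at 6, 8 for Q92 at 10 and 85 for Q140 at 10. With the wild types housed with Q20 mice alone the count was 1546 for Q92 at 10 and 1084 for Q140 at 10. Called genes with an estimated fold of at least 1.2 were 700 for Q92 at 6 and 370 for Q140 at 6. They were 336 for Q20 at 10, 79 for Q92 at 10 and 114 for Q140 at 10. With the DESeq2 Wald test the count was 36 for wild types at 6, 261 for Q92 at 10, 311 for trend at 10 and 42 for sex at 6. Without the libraries with no D code the count was 2 for wild types at 6, 50 for Q20 at 10, 138 for Q140 at 10, 49 for trend at 10 and 510 for Q140 by age. With no low-count filter the count was 346 for Q20 at 10 and 168 for Q140 by age.

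Without the knock-in libraries with wild-type-range Abhd1 the count was 8 for Q50 at 6, 74 for Q20 at 10 and 90 for trend at 10. With the cholinergic level as a covariate the count was 11 for Q92 at 6, 27 for Q140 at 6, 6 for wild types at 6, 3 for Q20 at 10, 180 for wild types at 10, 20 for trend at 6, 0 for Q92 by age (964 at unadjusted p below 0.05), 0 for Q140 by age (1156 at unadjusted p below 0.05), 1036 for age in wild type and 1 for list tests. Without the libraries above 13% mitochondrial counts the count was 1016 for Q140 at 6, 35 for wild types at 6, 574 for trend at 6 and 38 for sex at 6. The covariate is built from genes that include Chat, Lhx8, Slc10a4 and Slc5a7, so it removes their own variation by construction, and at 6 months its values in Q92 and Q140 mice did not overlap those of wild types. Single genes reversed with it: in Q92 mice at 6 months Arhgap36 to 0.19, Ramp3 to -0.12 and Nos1 to 0.0035, in Q140 mice at 6 months Lhx8 to 0.033, Tcf7l2 to 0.019 and Gad2 to 0.042, by age in Q140 mice Chat to -0.18 and Slc5a7 to -0.19, and with age in wild type Tac1 to 0.0079. With 3 surrogate variables Gm4459 turned to 0.068 and Sst to 0.014 with age in wild type. With the Q20 line as the reference, in which both genes also differed from wild type, Abhd1 turned to -0.16 in Q50 and -0.028 in Q92 mice at 6 months, and Atraid to 0.016 in Q50 and 0.053 in Q92 mice at 10 months. Of the list tests, 16 in the report, camera called 3 with an estimated and 79 with a preset correlation. Across genes with a mean of at least 5 CPM the correlation between the ages of the Q20 fold changes, 0.065 in the report, was -0.23.

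Leaving out 1 library gave 1 to 8 for Q50 at 6, 367 to 752 for Q140 at 6, 2 to 28 for wild types at 6, 74 to 1997 for Q20 at 10, 30 to 443 for Q92 at 10, 128 to 248 for Q140 at 10, 631 to 1755 for wild types at 10, 87 to 193 for trend at 10, 44 to 430 for Q140 by age called genes. For named genes it left 14840 of 15503 values called, and 663 were not. A block of the replicate number gave 600 genes with age in wild type, where the difference was taken at the first number of each age. The numbers do not pair the libraries: the median correlation between residuals of libraries with the same number was 0.0055 at 6 months and -0.0049 at 10 months, with lowest values of -0.46 and -0.37, and the best match had the same number in 14 of 48 and 9 of 47 libraries. Simulated counts show what the depth and the number of libraries limit, for genes of over 1 CPM with no difference in tissue or cohort. For Q140 at 6 months 95.5% of the genes changed 1.5-fold were recovered. For the Q140 effect by sex the share was 67.2% at 6 months and 59.7% at 10 months.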

Other observations

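The tests of the neighbourhood of Htt, of CAG length, of the genotype labels and of the cohorts in this part were chosen after the result was seen. The tests of surface tissue and of the L code for the myelin genes, and the splits of the samples, were chosen before.

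Genes of tissues that border the cortex were present in some libraries of most groups. The choroid plexus level (mean log2 CPM of 13 markers) was 1.86 ± 2.26 in Q140 and 1.46 ± 2.23 in Q92 mice at 6 months, against 0.93 ± 1.71 and -0.45 ± 0.33 in the wild types housed with Q20 and Q50 mice, and that list was not called in either line (adjusted p = 0.12 and 0.28). The pituitary level reached 6.40 in a Q50 library at 6 months and 5.09 in a Q92 library at 10 months, while the lowest libraries were at -5.08. Olfactory bulb genes were at -0.51 ± 0.20 in Q92 and -0.13 ± 0.54 in Q140 mice at 6 months, against 1.14 ± 0.63 and 1.24 ± 1.38 in the wild types, and at 1.59 ± 1.55 in Q92 mice at 10 months. In Q140_6mo_Male replicate 3 the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were the lowest of the 47 male libraries (log2 CPM 4.24, 4.07, 3.34 and 2.76, against next lowest values of 5.73, 5.46, 4.34 and 3.89), and male Xist did not exceed 0.41, where the female median was 10.3. Q50_6mo_Female replicate 4 and Q92_6mo_Male replicate 3 had 14.7% and 13.6% mitochondrial counts and differed from the others of their groups by chi-square values of 63.2 to 97.6 and 70.4 to 93.4 per gene (median of all pairs 10.2).

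The genes called in at least 6 of the 8 comparisons of a line with wild type lay near Htt, with 100% of the 5 within 10 Mb of it. The slope of Abhd1 was 0.16 per 100 repeats at 10 months (upper 95% limit 0.37), below the 1.22 that an effect of CAG length would need, which argues against that length as the cause for Abhd1. The location is consistent with flanking DNA inherited with the allele, whose sequence was not examined here. A wrong genotype label of Q50_6mo_Female replicate 1 could account for its Abhd1, since 0 of the 3 other genes called in that line and age lay beyond the wild-type range by over 1 SD on the knock-in side, where the rest of the line had 1 to 3. For Q20_10mo_Male replicate 4 the count was 1 of 2 (Gm2420), where the rest of the line had 1 or 2, so a wrong genotype label and a recombined chromosome cannot be told apart from it, and the margin of 1 SD was set after the values were seen (2 and 0 genes without it).

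Lower myelin genes in Q140 mice at 10 months were weighed against the tissue taken. The meningeal level predicts 15.8% of the fall from the 32 wild types (slope -0.093 ± 0.035 SE). The slope was -0.16 in the wild types at 6 months alone and -0.00036 in those at 10 months alone. In wild types of the age of the fall, the meningeal level thus hardly tracked the myelin level. This test therefore cannot decide whether more surface and less deep tissue was taken. With the L code as a factor the median of the myelin markers was -0.28, beside -0.26 without it, which argues against that code. Q140 mice were housed apart from the wild types, so a cohort difference cannot be told apart from an effect of the allele: the Q140 median at 10 months was -0.31 and -0.29 against each wild-type group of that age, and the median between the wild-type groups was 0.16 at 6 months and -0.0062 at 10 months. Loss or immaturity of oligodendrocytes is a biological explanation that was not tested.

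Other splits of the samples were drawn 100 times for each comparison, the real split included. The splits moved single libraries between groups, so a difference between cohorts or batches would also set the real split apart. They therefore do not tell an effect of the allele, of repeat length or of age from such a difference. In several comparisons no other split gave as many genes as the real one, a share of 1 in 100 that was not adjusted over the comparisons. These were Q20 mice at 6 months (real 3, highest of the others 2), Q92 (1387 and 480) and Q140 mice (624 and 178) at 6 months, the wild-type groups at 6 months (16 and 0) and 10 months (1252 and 107), Q50 (10 and 6) and Q140 mice (213 and 58) at 10 months, the trends (312 and 4 at 6 months, 157 and 3 at 10 months), sex at 6 months (21 and 14) and age in wild type (1753 and 605). For Q50 mice at 6 months (4 and 21), Q20 (775 and 2104) and Q92 mice (152 and 574) at 10 months and sex at 10 months (23 and 162), 2 or 3 splits did, the real one included. The highest split there called more genes than the real one, so chance cannot be excluded. This points to a structure among the samples whose source was not tested. The difference of the Q140 effect between the sexes was 0 genes at both ages, which all 100 splits reached (highest 24 and 1).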
